A study of Mus musculus with 24 samples.

How the data were processed

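Genomic DNA of 24 mouse lung adenocarcinomas was compared with DNA of normal ear skin by array comparative genomic hybridisation, in which 2 DNA samples compete for the same probes and the ratio of their signals follows the ratio of their copy numbers. Per the labels, the mice were F1 hybrids of the B6 and C3H strains, tumour DNA carried Cy5, ear skin DNA carried Cy3, and both samples of an array had the same sex. The groups were taken from the treatment in the labels: 5 tumours of non-irradiated mice (numbers 1 to 5), 7 after gamma rays (6 to 12), 6 after carbon ions (13 to 18) and 6 after neutrons (19 to 24), with whole-body exposure at 7 weeks of age. Doses are not given in the sources used here. The labels do not say whether each tumour came from a different mouse, so the p-values measure the spread between these tumours.

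The deposited scanner files hold 180880 spots per array, and 24 arrays were spread over 6 slides read on 2 days. These scan days are called scan 1 and scan 2. Slides 43 and 44 were read in scan 2 and the other slides in scan 1. Per the file headers, the positions of the probes are those of the mouse build mm9. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed signals are intensity values from which the background was subtracted, with a spatial trend removed and a linear dye normalisation within each array; the lowess dye term was 0 on every array. The deposited median spot and background signals are raw intensity values. The deposited log ratio column holds log10 of red over green and equals the ratio of the processed signals, so it was used only to check the direction. A deposited value table gives log2 ratios of the same arrays: each column correlated best with its own array (r from 0.928 to 1.00; highest r with any other array 0.769), with slopes from 0.861 to 1.00 and column medians from -0.02 to 0.02. Its direction and scale were therefore settled, while a further correction and the centring behind it stay unknown; it served as an alternative only.

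For the main setting, log2 of the tumour over the ear skin processed signal was taken per spot. Control spots and spots marked as outliers in either channel (106 to 695 per array) were left out, saturated spots (0 to 3 per array) were kept, and spots of 1 probe were averaged. This gave 170305 probes, of which 161460 lay on autosomes, 8723 on X and 122 on Y, with a median spacing of 10.8 kb. Each array was centred on its autosomal median, with no loess or quantile step; the medians removed ran from -0.02 to 0.05. Between 99.6% and 100.0% of spots were well above background in both channels, the median tumour signal was 984 to 1150 and the median ear skin signal 980 to 1137. The noise of 1 probe, taken from differences between neighbouring probes, had an SD of 0.11 to 0.23 on the log2 scale. The number of arrays limits the precision of every group value. No arrays were duplicates of each other (r between arrays from 0.131 to 0.770).

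Segments of constant log2 ratio were found per chromosome and tumour by optimal partitioning on squared error, with a penalty of 10 times the noise variance times the log of the number of probes and at least 10 probes per segment. Before partitioning, single probes over 3 noise SDs from the median of 11 probes were pulled in to that limit. A segment was a gain at a mean log2 ratio of at least 0.2 and a loss at -0.2 or below. The altered share of a tumour is the percent of the 2408 Mb of autosomes covered by probes that lies in gains or losses. A chromosome counted as gained or lost when at least 70% of its covered length did, and a segment of at most 3 Mb counted as focal. On simulated arrays the partitioning found 100% of whole chromosomes and of 500-probe segments at a level of 0.25, 37.5% of 50-probe segments at 0.25, and 58.3% of 15-probe segments at 0.5 but 0% at 0.25, with 0 false segments in 24 simulated tumours. The simulated noise was independent between probes, so false segments from noise shared by neighbouring probes were not covered.

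Group means of the altered share were compared by exact two-sided permutation tests over all arrangements of the tumours, with 7 comparisons in 1 Benjamini-Hochberg family, and 95% intervals from inverting the same tests. The gained share, the lost share and the number of altered segments were tested in the same way. Recurrent gains and losses were tested by rotating each tumour's calls along the 2397 autosomal bins of 1 Mb, 10000 times. Whole chromosomes seen in at least 3 tumours were tested by two-sided Fisher's exact tests. Medians of 2383 bins holding at least 10 probes were fitted with limma (lmFit, eBayes) in 1 model with 4 group means, where all irradiated is the mean of the 3 irradiated group means, and an adjusted p under 0.05 counted as a difference. In simulated bins, limma recovered between 74% (neutron against non-irradiated) and 89% (carbon against gamma) of those shifted by 0.3, and 98% to 100% of those shifted by 0.6, with 0 unchanged bins called. Each shift was given to every tumour of a group, in bins scattered at random. These rates therefore do not apply to whole-chromosome changes that only some tumours of a group carry.

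Genes were to be named by a rule fixed before the data were examined: Egfr, Cdkn2a, Trp53 and 1 further gene that is not reported here always, list genes altered in at least 4 tumours (at most 20, at most 3 per chromosome and list), list genes that differed between groups or else the 5 with the largest differences, regions of differing bins, and focal segments at a log2 ratio of -1 or below or of at least 1 (the 10 most extreme). The files carry no gene names, and the gene table at hand gives positions on GRCm38.p6, another build than that of the probes. Genes were therefore assigned to chromosomes only, and the rule was applied to whole chromosomes; all 125 genes of the 5 lists had a chromosome there, and ties were broken by name. The planned rotation test of the lists was replaced, after the data were examined, by a one-sided test of the pairs of list gene and tumour in which the gene's whole chromosome was gained or lost, against 100000 permutations of the chromosomes. Values per gene, windows of 50 kb and 1 Mb around genes, the antigen receptor loci and a correction for GC content were not run because they need gene or sequence positions on mm9.

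Alternatives were no centring, centring on the peak of the bin values, normexp (offset 50, on median in place of mean spot signals because only medians were at hand), the value table, only the 167018 probes well above background on all arrays, call thresholds of 0.1 and 0.3, at least 5 or 50 probes per segment, penalties of 5 and 20, other bin sizes, slide and sex terms, array weights, noise as a covariate, fits of only the groups compared, focal limits of 10 Mb, whole chromosomes at 90%, and each tumour left out. Added after the data were examined were settings for 2 tumours whose sex signals go against their labels, joined segments, focal counts without a variable chromosome 4 locus, 1 value per chromosome, sex taken from the signals, a test over 4 groups, tests of the number of whole chromosomes per tumour and of a shared chromosome 6 border, the lowest p that each Fisher's exact test could reach, the size of the chromosome 5 difference and arrangements of the labels within slides. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package.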

Results

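Copy number was measured in 24 lung adenocarcinomas of B6 and C3H hybrid mice, each against ear skin of the same sex per the labels. The set held 5 tumours of non-irradiated mice (2 female, 3 male), 7 tumours after gamma rays (3 female, 4 male), 6 after carbon ions (5 female, 1 male) and 6 after neutrons (1 female, 5 male). Gamma rays are photons that ionise sparsely, whereas carbon ions and neutrons deposit their energy along dense tracks. A log2 ratio of 0 means that tumour and ear skin gave equal signals relative to the autosomal median of the array. A gain or loss carried by only part of the cells gives a smaller ratio than one carried by all cells. The labels of 2 tumours, 17 and 23, go against the sex signals of both their channels, as described at the end, and they are named by their labels throughout.

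Loss of chromosome 4 and gain of chromosome 6 were the recurrent changes of these tumours, with and without irradiation. Chromosome 4 was lost as a whole in 17 of 24 tumours, at a mean log2 ratio of -0.42 ± 0.19 (SD, n = 17). In this count, carbon tumours 13 and 17 depend on centring on the median, as described below. The lost region past the rotation threshold ran over all 153 bins of chromosome 4 (3000001 to 156000000, mm9), and over 152 bins with peak centring. Chromosome 6 was gained as a whole in 10 tumours, at 0.41 ± 0.16 (SD, n = 10), and all 147 of its bins (3000001 to 150000000) passed the threshold. In the order non-irradiated, gamma, carbon and neutron, whole chromosome 4 was lost in 3, 5, 5 and 4 tumours and whole chromosome 6 gained in 3, 2, 4 and 1.

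The chromosome 4 losses were most frequent in the bin from 88000001 to 89000000, which was lost in 19 tumours, 3 of them non-irradiated, 6 gamma, 5 carbon and 5 neutron. Neutron tumour 22 had a loss of only 1.09 Mb there, from 87982535 to 89076517, at a log2 ratio of -0.38. The chromosome 6 gains were most frequent from 3000001 to 40000000, with 12 tumours. Neutron tumour 21 gained only this end of the chromosome, from 3131098 to 39517641, at 0.46. The rotation test gave p from 0.0001 to 0.0016 over the bins of chromosome 4 and from 0.0001 to 0.0005 over those of chromosome 6, where 0.0001 is the smallest value that 10000 rotations can give. Counts above 8 losses or 6 gains were rare under rotation (95th percentiles of the highest count). Loss counts are too low at the variable chromosome 4 locus described below. There, as in non-irradiated tumour 1, adjoining short segments each covered too little of a bin to be counted. With the call threshold at 0.1 or at 0.3, 115 bins of chromosome 12 joined the recurrent gains, and without gamma tumour 10, 52 bins of chromosome 5 joined the losses.

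**Figure D1:**
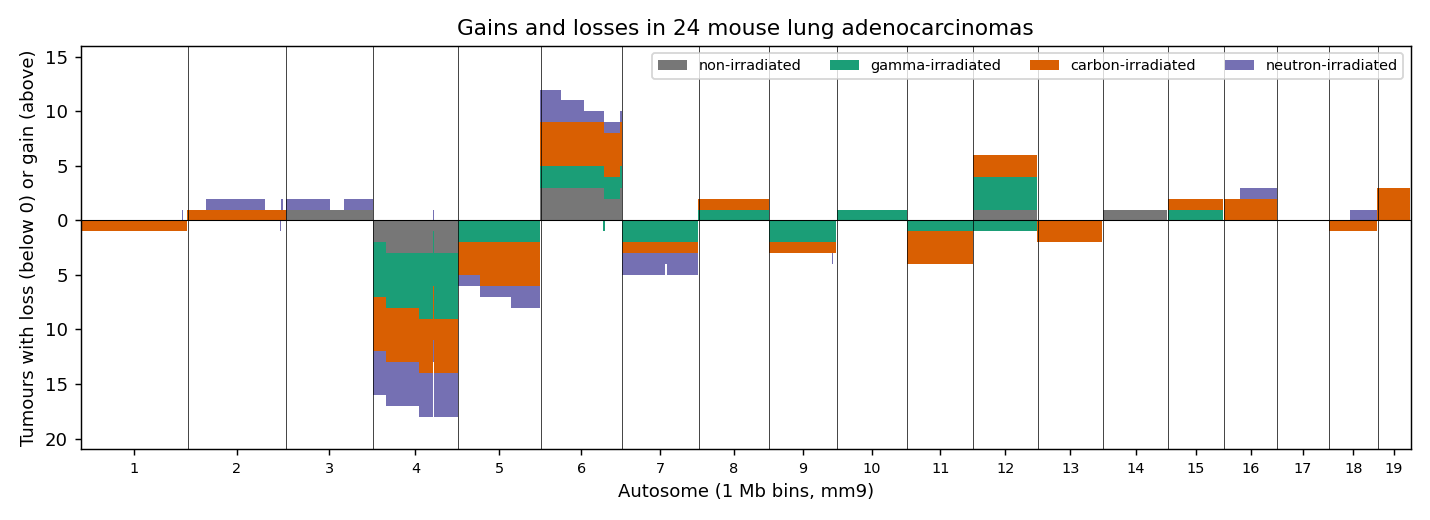
Number of tumours with a gain (above 0) or a loss (below 0) in each 1 Mb bin of the 19 autosomes (mm9), stacked by group. Losses split into several short segments within a bin, as at the variable chromosome 4 locus, are not all counted. Losses of chromosome 4 reach 19 tumours in 1 bin and gains of chromosome 6 reach 12 tumours, and both include all 4 groups.

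Other whole chromosomes changed in fewer tumours. Chromosome 5 was lost in 7 tumours (0 non-irradiated, 2 gamma, 4 carbon and 1 neutron), at -0.30 ± 0.10 (SD, n = 7). The losses of carbon tumours 13 and 17 among them rest on centring on the median, as described below. With whole chromosomes at 90%, the count was 6. Chromosome 12 was gained in 6 (1, 3, 2 and 0 in the same order), at 0.43 ± 0.16 (SD, n = 6), and chromosome 7 was lost in 5 (0, 2, 1 and 2). The carbon loss of chromosome 7, in tumour 17 at -0.33, depends on centring on the median too. Chromosome 11 was lost in 4 tumours (0, 1, 3 and 0), chromosome 9 was lost in 3 (0, 2, 1 and 0), and chromosome 19 was gained in 3 tumours, all of the carbon group. Gamma tumour 10 lay close to the threshold for both losses, with chromosome 9 at -0.20 (counted) and chromosome 11 at -0.19 (not counted). Carbon tumours 16 and 17 were also close for chromosome 11, both at -0.20 (counted). In tumour 17 chromosome 11 lay above the peak of the bin values (-0.34), so this loss rests on centring on the median. In gamma tumour 10 that peak lay at 0.12, and its chromosome 11 lay more than 0.2 below it. Of the 8 changes seen in at least 3 tumours, none passed Fisher's exact test between irradiated and non-irradiated tumours; the lowest p was 0.272 (chromosome 5, 7 of 19 against 0 of 5; adjusted p = 0.983). With 5 non-irradiated tumours, 7 of these 8 changes could not have passed for an excess after irradiation, chromosome 5 among them, and only the loss of chromosome 4 (14 of 19 against 3 of 5, exact p = 0.608) could, so that for the 7 an excess is left open. The 0 differences adjusted for 8 tests compare with 0 at an unadjusted p under 0.05.

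The study asks how tumours that arise after irradiation differ in copy number from those of untreated mice. Gains and losses covered 19.0% ± 16.4 (SD, n = 19) of the autosomes in all irradiated tumours and 10.3% ± 6.71 (SD, n = 5) in non-irradiated tumours. The lost share was 12.0% ± 10.0 against 3.60% ± 3.30, and the gained share 7.04% ± 8.49 against 6.67% ± 8.66. Irradiated tumours had lost 2.00 ± 1.83 (SD) whole chromosomes each and non-irradiated tumours 0.6 ± 0.548. The values of both groups overlapped: the non-irradiated tumours lay between 5.40% and 21.2% and the irradiated tumours between 0.0893% and 56.9%.

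None of these differences passed its test. The number of lost whole chromosomes, tested after the data were examined, differed by 1.4 (exact permutation p = 0.113). The altered share differed by 8.75 percentage points (95% interval -6.53 to 24.4; exact permutation p = 0.259, adjusted p = 0.408 over 7 comparisons), the lost share by 8.38 (exact p = 0.0793, adjusted p = 0.230) and the gained share by 0.376 (exact p = 0.933, adjusted p = 0.933). The number of altered segments was 6.95 ± 3.91 against 6.20 ± 3.35 (exact p = 0.745, adjusted p = 1). Within batches the altered share of irradiated minus non-irradiated tumours was 8.61 on slide 36, 12.0 on slide 38, 46.3 on slide 43 (1 tumour against 3), 2.97 in scan 1 and 17.5 in scan 2, and an exact permutation within slides gave p = 0.266. When the labels of the slide that holds tumours 17 and 23 were moved by 1 position, the difference was -0.281.

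**Figure D2:**
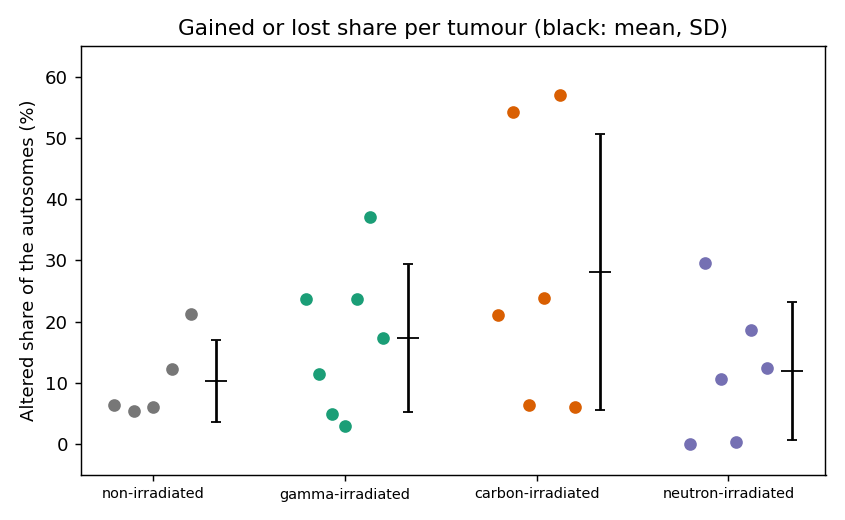
Altered share of the autosomes (percent, vertical axis) of each tumour by group, as points, with the group mean and SD in black. Group means run from 10.3% in non-irradiated to 28.1% in carbon tumours, and carbon tumours spread from 6.08% to 56.9%.

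After gamma rays, 17.3% ± 12.0 (SD, n = 7) of the autosomes were altered and 11.3% ± 8.68 lost, against 10.3% and 3.60% in non-irradiated tumours. Gamma tumour 11 had the most changes of its group (37.2%), with whole gains of chromosomes 8 and 12 and a whole loss of chromosome 5 among them, and gamma tumour 9 had the fewest (2.90%, on chromosome 4). The first rank rests on the call threshold and on centring on the median. In gamma tumour 10 (23.6%), chromosomes 7 and 9 were called lost with medians of -0.20. Chromosomes 3 (-0.20), 10 (-0.19), 11 (-0.19), 13 (-0.19) and 18 (-0.20) of this tumour were not. The peak of its bin values lay at 0.12, and each of these chromosomes lay more than 0.2 below that peak. Centring on the median therefore lowers the lost share of this tumour. The chromosome medians with the largest differences from non-irradiated tumours were those of chromosomes 6 (0.17 against 0.28), 4 (-0.36 against -0.25) and 5 (-0.11 against -0.01). The altered share differed by 7.03 percentage points (95% interval -6.52 to 20.8; exact permutation p = 0.280, adjusted p = 0.408) and the lost share by 7.74 (exact p = 0.0985, adjusted p = 0.230), neither beyond the spread between tumours. Only slide 36 held both groups (17.4, 1 tumour each; slide 42 held gamma tumours only), and the difference was -0.442 in scan 1, 19.3 in scan 2 and -0.120 with the labels of slide 38 moved.

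After carbon ions, 28.1% ± 22.5 (SD, n = 6) of the autosomes were altered, 17.0% ± 12.7 lost and 11.0% ± 11.9 gained. Carbon tumours 17 (56.9%) and 14 (54.2%) had the highest altered shares of all 24 tumours, while carbon tumours 15 and 18 had 6.33% and 6.08%. Tumours 13, 14 and 17 gained chromosome 19 as a whole, and tumours 13, 14, 16 and 17 lost chromosome 5. In tumour 16 the loss covered 72.9% of chromosome 5, close to the limit of 70%, and the chromosome median was -0.14. The peak of the bin values lay at -0.34 in tumour 17, at -0.12 in tumour 13 and at 0.08 in tumour 16. Chromosomes 4 and 5 lay less than 0.2 from that peak in tumours 17 (-0.35 and -0.34) and 13 (-0.25 and -0.22). These losses, and with them the lost share of the carbon group, therefore rest on centring on the median. The altered share differed from that of non-irradiated tumours by 17.8 percentage points (95% interval -5.62 to 42.1; exact permutation p = 0.134, adjusted p = 0.408) and the lost share by 13.4 (exact p = 0.0519, adjusted p = 0.230), neither past the threshold. The altered share differed by 14.7, 19.2 and 46.3 on slides 36, 38 and 43, by 13.3 in scan 1 and by 22.2 in scan 2. With the labels of slide 38 moved it differed by 4.28.

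After neutrons, 12.0% ± 11.2 (SD, n = 6) of the autosomes were altered and 7.65% ± 7.55 lost, against 10.3% and 3.60% in non-irradiated tumours. Neutron tumours 19 (0.0893%) and 22 (0.422%) had almost no large change, and chromosome 4 was at 0.00 and -0.01 in them. Neutron tumour 20 had the highest share of its group (29.6%), including whole changes of chromosomes 3, 4 and 7 and partial ones of chromosomes 5 and 18. The altered share differed by 1.7 percentage points (95% interval -11.2 to 15.3; exact permutation p = 0.764, adjusted p = 0.764) and the lost share by 4.05 (exact p = 0.225, adjusted p = 0.315). It was -6.24 on slide 36, -2.54 on slide 38, -1.88 in scan 1, 4.47 in scan 2 and -1.83 without tumour 20, so its direction was not settled; the same holds for thresholds of 0.1 (-3.79) and 0.3 (-1.42), peak centring (-0.275) and moved labels (-5.03).

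Between kinds of radiation, carbon tumours had the highest and neutron tumours the lowest mean altered share. Carbon exceeded gamma by 10.8 percentage points (95% interval -10.8 to 33.0; exact permutation p = 0.291, adjusted p = 0.408). This difference ran from 3.76 to 15.6 over the alternative settings and was 5.01 at the lowest with 1 tumour left out. Neutron minus gamma was -5.33 (-19.9 to 9.39; exact p = 0.427, adjusted p = 0.498) and neutron minus carbon was -16.1 (-40.1 to 6.56; exact p = 0.169, adjusted p = 0.408). None passed, nor did a permutation test over all 4 groups that was added after the data were examined (p = 0.179). Within slides, carbon minus gamma was -2.67 on slide 36 and -21.2 on slide 44, against the pooled direction, and 13.7 and 2.89 in scans 1 and 2. Neutron minus gamma was -23.6 and -14.8 on slides 36 and 44 and -1.44 and -14.8 in scans 1 and 2, and turned to 1.05 when the groups of tumours 17 and 23 were exchanged. Neutron minus carbon was -20.9, 7.22, -21.8 and 6.33 on slides 36, 37, 38 and 44, and -15.2 and -17.7 in scans 1 and 2. It shrank to -3.34 when the groups of tumours 17 and 23 were exchanged. By the labels carbon tumours were mostly female and neutron tumours mostly male, so sex goes with the kind of radiation here.

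Along the genome, no 1 Mb bin differed between groups in any of the 7 comparisons. With limma, 0 of 2383 bins had an adjusted p under 0.05; at an unadjusted p under 0.05 there were 17 bins for all irradiated, 2 for gamma, 193 for carbon and 10 for neutron tumours against non-irradiated tumours, 130 for carbon against gamma, 69 for neutron against gamma and 274 for neutron against carbon. The lowest adjusted p values were 0.711, 0.806, 0.468, 1.00, 0.908, 0.948 and 0.394 in that order. With 1 median per chromosome, which was added after the data were examined, limma also called 0; carbon tumours had chromosome 5 at -0.19 ± 0.17 and non-irradiated tumours at -0.01 ± 0.03 (SD; difference -0.18, SE 0.08, adjusted p = 0.344). The largest chromosome differences of neutron from non-irradiated tumours were those of chromosomes 6 (0.13 against 0.28) and 12 (0.01 against 0.14), with an adjusted p of 0.948 in limma.

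The calls on chromosomes 5 and 9 depended on the model. With slide as a fixed term, limma called 95 bins for all irradiated, 102 for gamma and 51 for carbon tumours against non-irradiated tumours, and 0 in the other 4 comparisons, while slide as a random block gave 0 in all 7 (correlation -0.01). All of these bins were lower after irradiation and on chromosome 5, except 1 bin of chromosome 9 in the gamma comparison. Over all 147 bins of chromosome 5 the median difference was -0.30 (SE 0.08) for all irradiated, -0.42 (SE 0.11) for gamma and -0.26 (SE 0.08) for carbon tumours, with lowest adjusted p values from limma of 0.0151, 0.00781 and 0.0393, against -0.11 (SE 0.07), -0.10 (SE 0.08) and -0.19 (SE 0.09) without a slide term. Only slide 36 held both gamma and non-irradiated tumours, 1 each. Slide 42 held only gamma tumours 7, 8, 9 and 10, so with a fixed slide term they add nothing to the gamma difference. Their chromosome 5 medians were -0.001, -0.03, -0.05 and 0.11. Among gamma tumours, the difference of -0.42 therefore rests on tumours 6, 11 and 12, with chromosome 5 at -0.26, -0.42 and -0.11. The 7 tumours with a lost chromosome 5 were 6, 11, 13, 14, 16, 17 and 23, among them both tumours of doubtful label. Without tumours 17 and 23 this model called 0 bins for all irradiated and for carbon tumours and 146 for gamma tumours, 76 of them on chromosome 5 and 70 on chromosome 9, although the difference on chromosome 5 moved little, to -0.27 (SE 0.08) for all irradiated, -0.40 (SE 0.11) for gamma and -0.24 (SE 0.08) for carbon tumours. With the groups of these 2 tumours exchanged it called 103, 128 and 0 bins of chromosome 5 for all irradiated, gamma and carbon tumours, and 6 of chromosome 9 for gamma tumours. Without slide 38 it called 84, 120 and 49 in the same order, and with the labels of that slide moved 0, 1 and 0 (differences -0.16, -0.30 and -0.14, SE 0.09, 0.13 and 0.09), while 113, 120 and 109 and then 115, 113 and 97 bins of chromosome 9 were called, all lower after irradiation.

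Among the genes named by rule, 6 lay on chromosome 4, which was lost in 17 tumours: Cdkn2a and Cdkn2b, which encode inhibitors of cyclin-dependent kinases, Arid1a (a chromatin remodeller), Mycl1 (a Myc family member), Nbn (break repair) and Cdc20 (mitotic exit). On chromosome 6, gained in 10 tumours, lay, among others, the oncogenes Braf and Met, the suppressors Cdkn1b and Foxp1, the repair genes Fancd2 and Rad52, the spindle checkpoint gene Mad2l1 and Sftpb, which encodes surfactant protein B. Brca2, Chek2, Cdk6 and Hopx lay on chromosome 5, lost in 7 tumours. Egfr, a growth factor receptor, and Trp53, the gene of the p53 tumour suppressor, lay on chromosome 11, which was lost in 4 tumours and gained in 0. The mean chromosome log2 ratio over all 24 tumours was -0.32 for chromosome 4, 0.19 for chromosome 6 and -0.10 for chromosome 5. These values are of whole chromosomes, and the copy number at the genes themselves was not measured separately.

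No gene list lay on changed chromosomes beyond chance. The 33 autosomal suppressors made 129 pairs of gene and tumour on lost chromosomes against a mean of 71.1 in permutations (one-sided permutation p = 0.0580, adjusted p = 0.419 over 10 tests), with Cdkn2a and Arid1a on chromosome 4 as examples, and 37 against 52.1 on gained chromosomes (adjusted p = 0.826). The 36 oncogenes made 90 pairs on gained chromosomes against 56.9 (permutation p = 0.0837, adjusted p = 0.419), with Braf and Met as examples, and 76 against 77.6 on lost ones (adjusted p = 0.807). The 25 break repair genes made 69 pairs on lost chromosomes against 53.7 (permutation adjusted p = 0.545) and 28 on gained ones against 39.5 (adjusted p = 0.826). The 20 genes of mitosis and the nuclear envelope made 36 pairs on lost chromosomes against 43.2 (permutation adjusted p = 0.826) and 31 on gained ones against 31.6 (adjusted p = 0.807). The 14 lung lineage genes made 17 pairs on lost chromosomes against 30.3 (permutation adjusted p = 0.826) and 30 on gained ones against 22.1 (adjusted p = 0.545).

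Focal changes were few outside 1 locus of chromosome 4 (111742887 to 113993176). Irradiated tumours had 2.21 ± 2.35 (SD, n = 19) focal segments each and non-irradiated tumours 2.60 ± 2.88 (SD, n = 5), a difference of -0.389 (exact permutation p = 0.750). The strongest focal gains were those of neutron tumour 22, on chromosome 1 from 189395038 to 190316102 (2.96) and on chromosome 2 from 168987493 to 170454412 (2.83); a longer gain on chromosome 2 from 171044275 to 174984258 reached 2.80 in the same tumour. Outside the locus, focal losses at -1 or below were seen in gamma tumour 11, on chromosome 11 from 70989862 to 71107103 (-1.73) and on chromosome 6 from 39605486 to 39866777 (-1.04), and in non-irradiated tumour 1 on chromosome 4 from 21659397 to 21756151 (-1.28). Carbon tumour 16 gained chromosome 6 from 39294398 to 39595758 (1.06). The direction of the difference in focal counts turned with neighbouring segments joined (0.389), with the locus left out (0.189), with normexp (0.2) and without non-irradiated tumour 1 (0.711).

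The chromosome 4 locus stood apart from its chromosome in many tumours. Of its 139 probes, 75 varied strongly between tumours, and it was the only such locus in a search of the autosomes that was designed after the locus had been noticed. The locus median reached -1.79 in gamma tumour 12, -1.68 in gamma tumour 11 and -1.42 in non-irradiated tumour 1, where chromosome 4 was at -0.58, -0.43 and -0.26. It was at 0.02 in gamma tumour 6 and -0.02 in non-irradiated tumour 4, where chromosome 4 was at -0.25 and -0.24. In neutron tumour 19 it was at 0.70 with chromosome 4 at 0.00. Of the 8 segment borders that at least 3 tumours shared, 7 lay in or within 0.1 Mb of this locus.

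**Figure D3:**
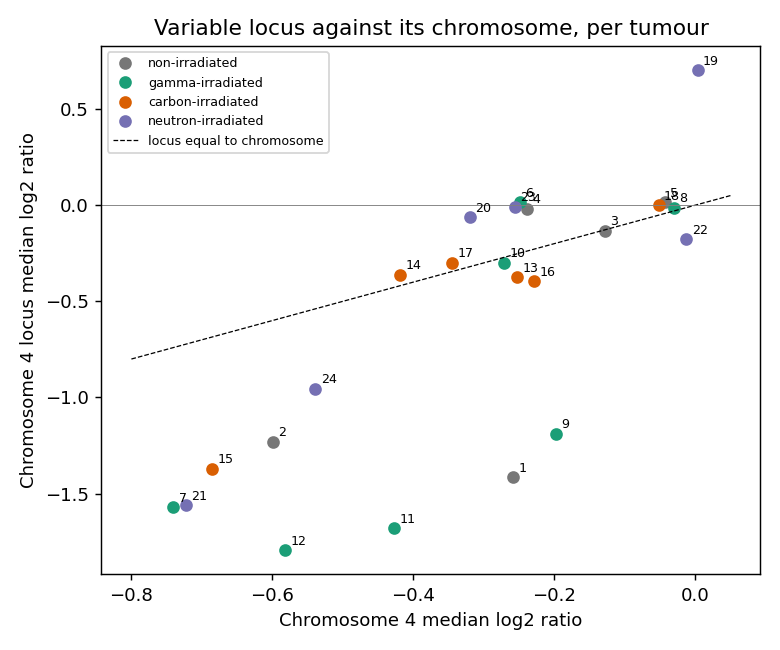
Median log2 ratio of the variable chromosome 4 locus (vertical axis) against that of chromosome 4 (horizontal axis) for each numbered tumour, coloured by group, with a dashed line where both are equal. Tumours of every group lie far below the line, and neutron tumour 19 lies at 0.70 with its chromosome at 0.00.

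A border on chromosome 6, between probes ending at 39595758 and starting at 39605486, was shared by 3 tumours. Gamma tumour 6 had a loss at -0.62 that began there and ran to 40123430, gamma tumour 11 had the loss at -1.04, and the gain of carbon tumour 16 ended there. Over 15 probes on each side the step from left to right was -0.73, -1.39 and -0.98 in these tumours, while the other 21 tumours had a median step of -0.04 and none beyond -0.14. These medians miss borders that lie nearby. The gain of neutron tumour 21 at 0.46 ended at 39517641, so most of the 15 probes left of the shared border lay outside it (step -0.09). All 3 were irradiated, 3 of 19 against 0 of 5, the most uneven division that 3 tumours allow toward irradiation, which gives p = 1 in Fisher's exact test, added after the border was seen, so that a relation to irradiation is left open.

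**Figure D4:**
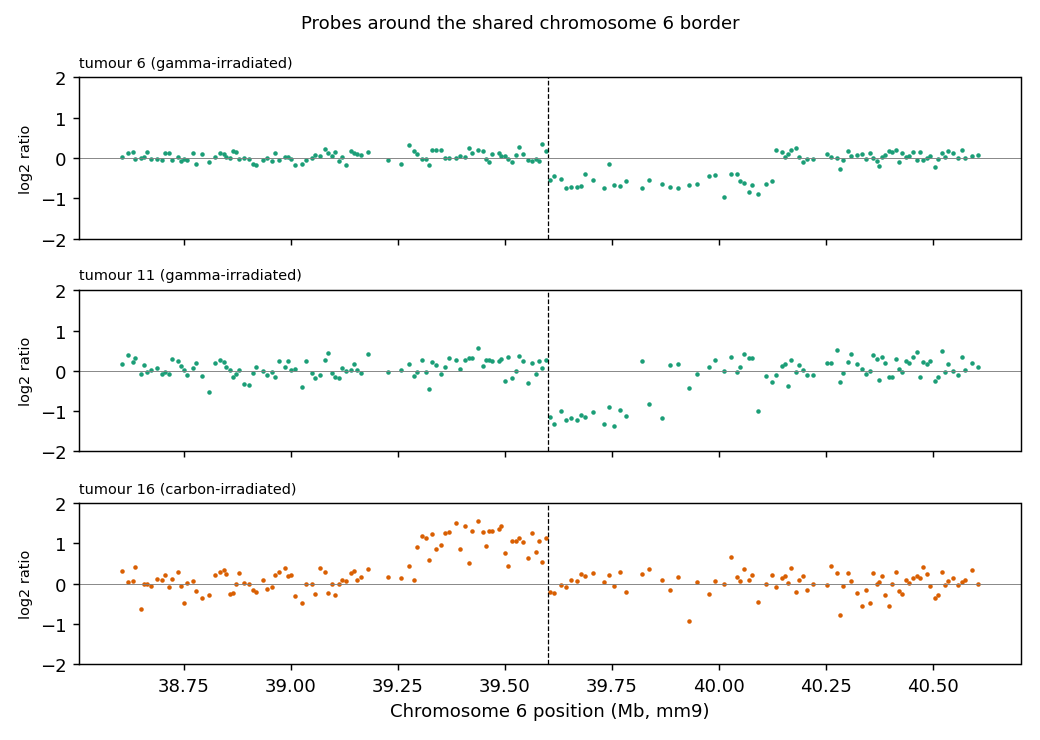
Log2 ratio of single probes (points) against position on chromosome 6 (Mb, mm9) in tumours 6, 11 and 16, with the shared border as a dashed line. The losses of gamma tumours 6 and 11 start at the border and the gain of carbon tumour 16 ends at it.

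The sex chromosomes were set apart from the comparisons. Ear skin of the 10 tumours labelled female other than tumour 17 had Y probe signals from -2.39 to -1.14 (log2 against the mean of all channels), and ear skin of the 12 tumours labelled male other than tumour 23 from 1.10 to 1.37. Ear skin of the carbon tumour labelled 17, a female, was at 1.38, and that of the neutron tumour labelled 23, a male, at -0.97. Both lay on slide 38. X was at -0.43 in carbon tumour 14, -0.39 in carbon tumour 18, -0.39 in neutron tumour 20, -0.27 in gamma tumour 9 and -0.21 in gamma tumour 10, and Y was at -1.17 in the tumour labelled 17.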

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

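The tests of the sex signals were chosen after the result was seen. Single tumours stood apart from the rest of their group in 8 of 44 groups and measures looked at. The limit used is set so that chance marks about 1 in 20 groups of independent, normally distributed values. Shares and chromosome medians here need not be distributed in that way. The rate was not tested here, and several measures came from the same tumours. Non-irradiated tumour 5 had a gained share of 21.2% and chromosome 12 at 0.73, and gamma tumour 11 had a gained share of 19.7%. In the neutron group, tumour 24 had chromosome 6 at 0.49, the tumour labelled 23 had chromosome 5 at -0.27, and tumour 20 had X at -0.39. Non-irradiated tumour 3 had X at 0.10. Carbon tumour 15 had 4 focal segments, all in the variable chromosome 4 locus.

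On X and Y, which no comparison used, 7 values of irradiated tumours lay below -0.2 and below all values of the 5 non-irradiated tumours. X was at -0.43 in carbon tumour 14, -0.39 in carbon tumour 18, -0.39 in neutron tumour 20, -0.27 in gamma tumour 9 and -0.21 in gamma tumour 10. Y was at -0.22 in carbon tumour 13 and at -1.17 in the tumour labelled 17. The peak of the autosomal bin values lay at -0.12 in tumour 13, so its Y value passes -0.2 only through centring on the median. Whether such changes differ between groups was not tested.

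The tumours labelled 17 (carbon, female) and 23 (neutron, male) went against the sex in their labels. A change of the sex chromosomes in the tumour is argued against, because the ear skin channel of the tumour labelled 17 had a Y signal of 1.38, like ear skin of males. An exchange of labels or arrays may explain it: 2 tumours of the same slide went against their labels in opposite directions, as an exchange between them or a move of labels by 1 position would give. Both stay open, and the groups of these tumours, as well as those of the other tumours on slide 38, cannot be settled from the signals. No other biological explanation was tested.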

How the results depend on the processing

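Settings for the tumours labelled 17 and 23 and their slide, joined segments, the left-out locus and slide terms combined with these were chosen after the data were examined. Tumours left out singly apart, 119 alternative values of the altered share kept their direction, 7 turned, and none passed the threshold. Neutron minus non-irradiated (1.7) turned to -0.275 with peak centring, -3.79 at a call threshold of 0.1, -1.42 at 0.3 and -5.03 with the labels of slide 38 moved by 1 position. The moved labels also turned all irradiated minus non-irradiated (8.75) to -0.281 and gamma minus non-irradiated (7.03) to -0.120, and exchanging the groups of the 2 tumours turned neutron minus gamma (-5.33) to 1.05. With each tumour left out in turn, the altered share differences ran from 6.65 to 11.5 (all irradiated), 3.72 to 9.76 (gamma), 12.0 to 22.2 (carbon) and -1.83 to 4.43 (neutron, reversed without tumour 20) against non-irradiated tumours, 5.01 to 15.2 (carbon minus gamma), -8.86 to -2.02 (neutron minus gamma) and -20.5 to -10.3 (neutron minus carbon). Recurrent gains covered 147 bins under every setting except thresholds of 0.1 and 0.3, where 115 bins of chromosome 12 made it 262; without single tumours, gains stayed at 147 and losses ran from 153 to 205. The focal difference (-0.389) turned to 0.2 with normexp, 0.389 with joined segments and 0.189 without the chromosome 4 locus, and ran from -1.04 to 0.711 without single tumours (reversed without tumour 1). Bins that differ were 0 (limma) in 149 alternative values and with each tumour left out. The 12 others all had slide as a fixed term: 95, 102 and 51 for all irradiated, gamma and carbon against non-irradiated; 197, 240 and 158 without slide 38; 115, 114 and 97 with its labels moved; 103 and 134 (carbon 0) with the groups exchanged; and 146 for gamma (others 0) without tumours 17 and 23. These counts are not of the same bins: with moved labels 1 bin at most lay on chromosome 5, the rest on chromosome 9. Where no construction is named, the cause was not tested. No paired analysis was possible because each tumour has a number of its own. A GC correction, gene windows and the planned list test were not run. Dim signal limits little here, since at least 99.6% of spots were well above background.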

Other observations

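Of the tests in this part, those of dim probes and of borders placed at random were set before their results were seen; all others were chosen after. The 2 tumours with the most altered genome were carbon tumours of different slides and shared several whole-chromosome changes: both 14 and the tumour labelled 17 gained chromosomes 6, 12, 16 and 19 and lost chromosomes 4, 5, 11 and 13. In the tumour labelled 17 the peak of the bin values lay at -0.34, less than 0.2 from each of these lost chromosomes. The shared losses therefore rest on centring on the median. Neutron tumour 22 was of the opposite kind, with 0.422% of the autosomes altered but 3 gains at 2.80 or above on chromosomes 1 and 2. The difference between irradiated and non-irradiated tumours in altered share was compared between the sexes: males minus females gave -16.0 percentage points by the labels (permutation p = 0.102) and -7.94 with sex taken from the signals (permutation p = 0.432), neither past the threshold. Sex was permuted over all irradiated tumours together. By the labels, carbon tumours were 5 female and 1 male and neutron tumours 1 female and 5 male. This contrast therefore mixes sex with the kind of radiation.

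The chromosome 4 locus from 111742887 to 113993176 lay far from the median of its chromosome in tumours of all 4 groups. Independent deletions in each tumour are argued against, since in 7 tumours the low stretch ended between the same neighbouring probes (113561209 and 113574704). Another border shared by 7 tumours (112480643 and 112487676) divides 2 low segments and cannot decide this. Whether unequal response of the probes places such borders was not tested. Dim probes are argued against, since 10 tumours still lay over 0.3 from chromosome 4 with only bright probes. A candidate explanation was loss of 1 parental copy of a sequence that only 1 of the 2 parental strains carries, which predicts 2 possible values per tumour; 8 of the 17 tumours with a lost chromosome 4 lay over 0.3 from both, so this simple form is argued against as well. A strain difference combined with copy-neutral changes, mixed clones or compressed ratios was not modelled and stays open, as does any role of irradiation, with non-irradiated tumours 1 and 2 among the lowest values.

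The chromosome 6 border at 39595758 and 39605486 was shared by gamma tumours 6 and 11 and carbon tumour 16. A step between these probes on every array is argued against by the median step of -0.0440 in the other 21 tumours, and a strain difference uncovered by chromosome 6 gains by a largest distance of 0.0871 from the chromosome median in the 10 tumours that gained it. In 10000 draws of borders placed at random, at most 2 tumours shared a position (p = 0.0001, the smallest that permutation of this size can give); the draws treat all positions between probes alike. A preferred site of breakage or selection for a sequence beside the border may therefore be considered as a hypothesis, found and tested on the same data. The gain of neutron tumour 21 ended nearby on the left, at 39517641, and was not counted as sharing the border. Losses on one side and gains on the other leave open which sequence would matter. A relation to irradiation is left open, because 3 of 19 against 0 of 5 is the most uneven division toward irradiation and gives a Fisher's exact p of 1.

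For the bins that differ, limma's real count was 0 in all 7 comparisons, so that 100 of 100 splits of the tumours had to give as many and the splits decide nothing about chance. The highest counts of the other splits were 153 for all irradiated, 118 for gamma, 58 for carbon and 48 for neutron tumours against non-irradiated tumours, 310 for carbon against gamma, 148 for neutron against gamma and 78 for neutron against carbon. For the model with slide as a fixed term, 3, 2 and 2 of 100 arrangements of the labels within slides gave as many bins as the 95, 102 and 51 called for all irradiated, gamma and carbon tumours, with highest other counts of 124, 149 and 144. This model is 1 of many that were fitted, its arrangements were drawn after its counts were seen, and lower chromosomes 5 and 9 in irradiated tumours may be followed up only as a hypothesis. Its calls on chromosome 5 for all irradiated tumours numbered 95, with 84 of 197 bins there without slide 38, 0 of 0 without tumours 17 and 23, 103 of 103 with their groups exchanged, and 0 of 115 with the labels of slide 38 moved; the remaining bins lay on chromosome 9.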
